A study of Mus musculus with 6 samples.

How the data were processed

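RNA was measured in 6 libraries of 4T1 cells, a mouse mammary carcinoma line, in 2 groups of 3: vehicle, and KIRA6 at 1 µmol/L, each for 4 h. Per the labels' protocols, polyadenylated RNA was selected on oligo(dT) beads and the libraries kept strand information by the dUTP method. The submitters' processing notes name cutadapt 1.9.1, HISAT2 2.2.1, HTSeq 0.6.1, DESeq2 1.34.0 and the build GRCm39. Their settings, including the strand setting of the counting, are not given in the sources used here. The authors deposited FPKM, which scales the fragments of a gene by its exonic length and by the total of the library, for each gene and library, with 2 decimals, beside the gene's exonic length and its GRCm39 coordinates. The table holds 56691 genes, of which 34396 were at 0 in all 6 libraries, and no pair of libraries was identical.

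The depth was recovered from the steps between the low values of short genes, since FPKM times length is a whole multiple of what 1 fragment is worth. In each library 97.9% to 100% of 2195 to 2558 checked values came out within 0.1 fragment of a whole number. FPKM times length summed to the same total in every library, so the deposited values are scaled to the fragments assigned to genes. A count of 3 fragments, the upper limit that a count of 0 allows, was taken as the floor, and it covers counting error only. Differences between genes in read sharing stay in the values: Prl2c3, H2-T23, H2-Q4, Gbp2, Hspa1b and Ftl1 have near-identical copies, so their levels are uncertain.

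The test was written before the data were examined. Log2(FPKM + 0.5) was fitted with limma 3.58.1 in R 4.3.3, with KIRA6 against vehicle as the only term, an intensity trend and robust empirical Bayes, two-sided, with Benjamini-Hochberg adjustment. Genes with a mean of at least 0.5 FPKM over the 6 libraries were tested, 11778 in all, and an adjusted p below 0.05 was called. A fold change is on the log2(FPKM + 0.5) scale, which understates the change of low genes. Errors are the SD between the 3 libraries of a group for FPKM and the limma standard error (SE) for log2 fold changes. The labels do not say that the libraries came from separate cultures, so p-values measure only the spread between these samples, which may be technical. A permutation of 3 against 3 libraries cannot give a p below 0.1, so single genes were judged by limma alone.

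Before the data were examined 21 gene lists were fixed, and the 20 with at least 3 tested members were tested with camera at a preset correlation between genes of 0.01, adjusted over the lists. Camera asks whether a list moved relative to all other genes. Camera with an estimated correlation and fry, which asks whether a list's genes moved one way on balance, stand beside it. Members were also adjusted over the list alone. Genes named in the text follow a rule fixed at the same time. It takes the 8 increases and 8 decreases of largest log2 fold change among called genes with a mean of at least 1 FPKM, groups that did not overlap and an established symbol. It adds 16 genes named whatever their values, and up to 3 called members of each list with the smallest p. Members named beyond these, to complete a count of 5 or fewer or as further examples, were chosen after their values were seen.

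Gene types and GC content came from GENCODE M21 by gene identifier, which matched 52073 identifiers (91.9%), and no coordinate was taken from it. Alternatives fixed in advance changed the pseudocount, the filter, the scaling between libraries, the empirical Bayes settings and the library weights, added a replicate block, and left out each library in turn. Those chosen after seeing the data were limma-voom on fragments estimated from the recovered depth, a fit without Vehicle replicate 3 and KIRA6 replicate 1, the first component of the within-group residuals as a covariate, and a correction for GC content and length with and without the block. The planned test of raw counts was not run because the deposited values are FPKM.

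The steps were tested on simulated data with 200 of 11778 genes changed. Each gene had its own within-group spread from these libraries, drawn independently of the other genes. For KIRA6 against vehicle, limma recovered 6% of 50 genes changed 1.5-fold, 34% of 50 changed 2-fold, 82% of 50 changed 4-fold and 92% of 50 changed 8-fold, and 5 of 112 calls were false. Camera called 1 list, the 1 that had been shifted. The real libraries instead shared an axis with 81.3% of the within-group variance, and 23.6% of tested genes were called. False calls of limma and camera under such shared variation were therefore not measured, and the recovered shares hold only for the simulated setting. Most simulated changes of 2-fold or less were missed, so a gene that was not called may still have changed by that much.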

Results

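KIRA6 is a small molecule that binds the kinase domain of IRE1α, a sensor of protein folding stress in the endoplasmic reticulum (ER), and lowers its RNase activity. The series concerns KIRA6, suppressive myeloid cells and resistance to blockade of PD-1. Its RNA data ask which transcripts of the 4T1 tumour cells themselves differ after 4 h with KIRA6 at 1 µmol/L. There were 3 vehicle and 3 KIRA6 libraries. The vehicle libraries held an estimated 18202350, 16497350 and 18583400 fragments assigned to genes, and the KIRA6 libraries 21347400, 18216050 and 19847800. Genes above 0 numbered 16474 to 16843 in the vehicle and 17801 to 18060 in the KIRA6 libraries. Mitochondrially encoded genes took 1.75% to 2.03% of the fragments in the vehicle and 2.66% to 3.25% in the KIRA6 libraries.

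The first principal component, with 56.0% of the variance, separated vehicle from KIRA6. The second, with 35.1%, set Vehicle replicate 3 (−55.9) and KIRA6 replicate 1 (44.5) apart from the rest of their groups. Correlations of log2 values across genes ran from 0.936 to 0.992 within the vehicle group and from 0.950 to 0.986 within the KIRA6 group. Between the groups they ran from 0.889 (Vehicle replicate 3 with KIRA6 replicate 1) to 0.952 (Vehicle replicate 1 with KIRA6 replicate 1). The ranges overlapped, but the highest correlation of every library was with a library of its own group. KIRA6 replicate 1 correlated slightly more with Vehicle replicate 1 (0.952) than with KIRA6 replicate 3 (0.950).

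**Figure D1:**
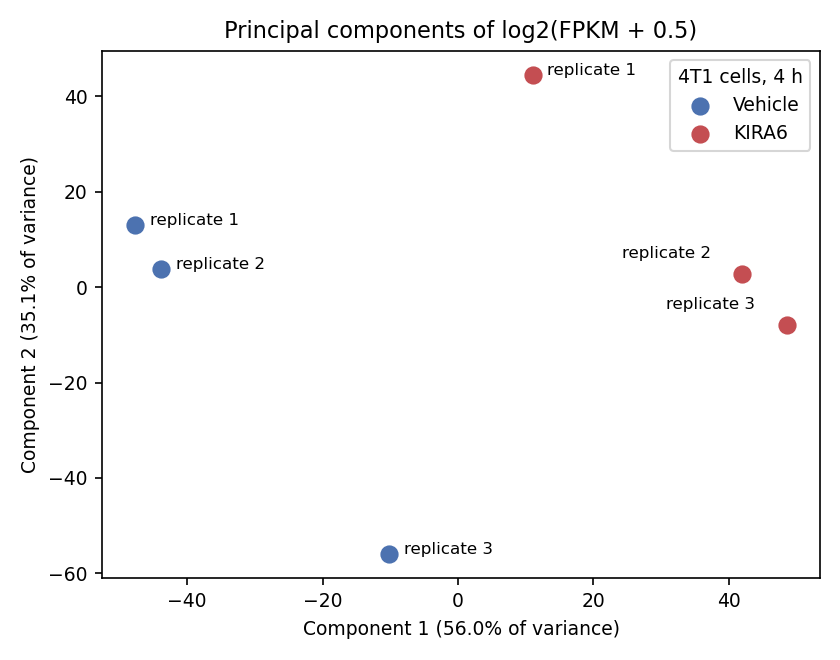
The 6 libraries on the first 2 principal components of log2(FPKM + 0.5), with the percent of variance on each axis, vehicle in blue and KIRA6 in red. The groups lie apart on the first component, and Vehicle replicate 3 and KIRA6 replicate 1 lie at opposite ends of the second, at −55.9 and 44.5.

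KIRA6 changed a wide set of transcripts. Of the decreases, that of Dusp6, a phosphatase that switches off ERK and is itself induced by ERK, was the largest among the genes the naming rule admits. Dusp6 (ENSMUSG00000019960, chromosome 10, 99099093 to 99103351 on GRCm39) fell from 42.8 ± 2.94 FPKM in vehicle to 1.30 ± 0.0709 FPKM with KIRA6 (SD, n = 3 each), a log2 fold change of −4.59 ± 0.13 (SE, adjusted p = 6.679e-05). The ETS factor Etv5 fell from 16.6 ± 7.21 to 0.327 ± 0.115 FPKM and the signalling regulator Rgs16 from 27.7 ± 0.427 to 1.10 ± 0.251 FPKM. The EGF receptor ligand Areg fell from 22.5 ± 0.406 to 1.08 ± 0.253 FPKM, and cyclin D1 (Ccnd1) from 469.2 ± 10.5 to 33.4 ± 2.56 FPKM. The other 3 of the 8 leading decreases were Ccn2, the cytokine gene Il24 and the AP-1 subunit Fosl1, with log2 fold changes of −3.26, −3.08 and −2.98. Adjusted p of the 8 ran from 6.679e-05 for Dusp6 to 0.002387 for Fosl1.

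The leading increases were Lrrc75b, from 0.460 ± 0.132 to 26.9 ± 1.67 FPKM, and Bmf, a pro-apoptotic member of the BCL2 family (chromosome 2, 118359238 to 118380168), from 0.127 ± 0.0462 to 13.0 ± 1.62 FPKM. Their log2 fold changes were 4.84 ± 0.16 and 4.42 ± 0.16 (SE, adjusted p = 7.871e-05 and 8.664e-05). The death receptor gene Fas rose from 0.370 ± 0.0624 to 10.02 ± 2.2 FPKM. Cpt1a, which admits long-chain fatty acids to mitochondrial oxidation, rose from 1.77 ± 0.329 to 22.3 ± 2.93 FPKM. Ccng2, an atypical cyclin, rose from 2.26 ± 0.621 to 21.7 ± 3.46 FPKM. Artn, Mgst1 and Prl2c3 had log2 fold changes of 3.05, 3.01 and 3.19, and Prl2c3 is uncertain because near-identical genes of its family share reads. Adjusted p of the 8 ran from 7.871e-05 for Lrrc75b to 0.002485 for Prl2c3.

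In total 2783 of 11778 tested genes (23.6%) were called by limma, 1843 higher and 940 lower with KIRA6. Of these, 1172 changed at least 2-fold, 780 higher and 392 lower. The groups did not overlap for 4928 genes (41.8%), where chance gives 10%. The median tested gene had a log2 fold change of 0.16, which median-ratio scaling of the libraries set to −0.008. That scaling called 1296 higher and 1438 lower, so the share of higher calls was 47.4% in place of 66.2%. It was 48.9% with quantile normalization and 48.9% with the GC and length correction. The direction of a single gene near this shift therefore depends on the scaling. The count of called genes was 1622 without Vehicle replicate 1, 1268 without Vehicle replicate 2, 1211 without KIRA6 replicate 2 and 1554 without KIRA6 replicate 3. It was 6610 without Vehicle replicate 3 and KIRA6 replicate 1 together. These libraries were left out because they lay apart, which lowers the within-group spread, so a higher count was built in.

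**Figure D2:**
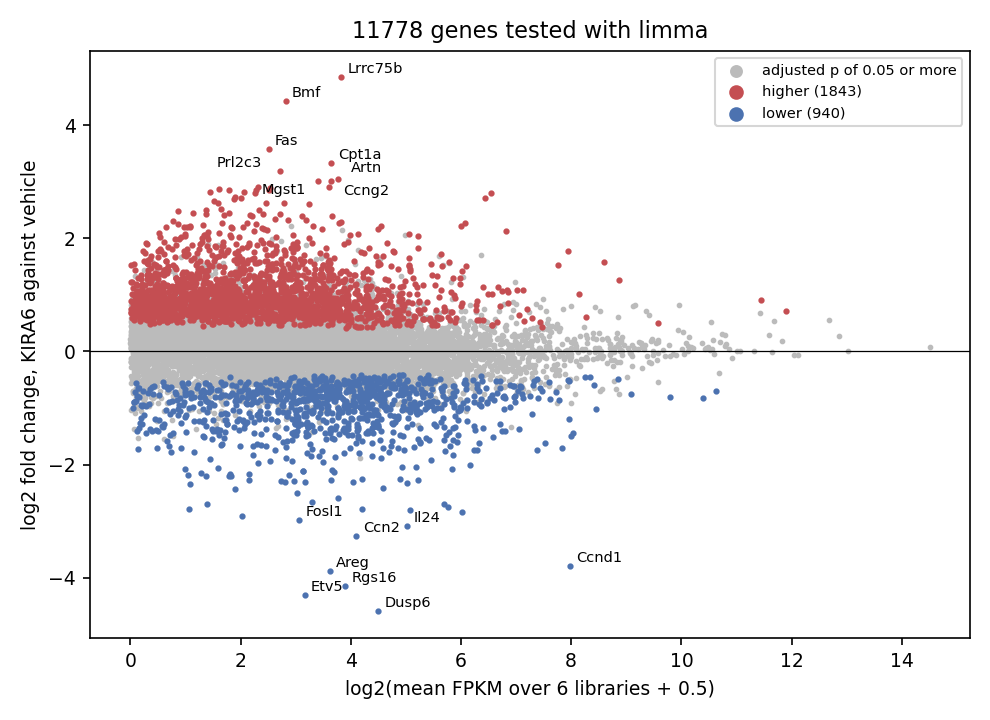
Each point is 1 of 11778 tested genes, with log2(mean FPKM + 0.5) over the 6 libraries on the x axis and the log2 fold change of KIRA6 against vehicle on the y axis. Red and blue points are the 1843 higher and 940 lower genes by limma, and the 16 leading genes are named, with Dusp6 at −4.59 and Lrrc75b at 4.84.

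The first question is whether transcripts downstream of IRE1 differed. Ern1, which encodes IRE1α (ENSMUSG00000020715, chromosome 11, 106285476 to 106378678 on GRCm39), had 3.71 ± 2.27 FPKM in vehicle and 2.63 ± 0.875 FPKM with KIRA6. Its log2 fold change was −0.34 ± 0.40 (SE, adjusted p = 0.582), within the spread between libraries, and 0.071 without Vehicle replicate 3, which alone had 6.33 FPKM. Total Xbp1, whose mRNA IRE1α splices (ENSMUSG00000020484, chromosome 11, 5470659 to 5475893), had 17.7 ± 2.74 and 26.3 ± 3.45 FPKM, a log2 fold change of 0.56 ± 0.17 (SE) that missed the threshold (adjusted p = 0.0566). Spliced and unspliced Xbp1 cannot be separated in gene-level FPKM. The XBP1s target Dnajb9 had 3.21 ± 0.732 and 4.68 ± 0.424 FPKM (adjusted p = 0.1026), and the ER chaperone Hspa5 had 327.7 ± 8.62 and 298.8 ± 18.7 FPKM (adjusted p = 0.4909).

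Of the 29 tested XBP1s-dependent ER genes 2 rose and 3 fell, and 2 and 2 when adjusted over the list alone. Arfgap3, which acts in Golgi transport, rose from 1.71 ± 0.507 to 5.58 ± 1.08 FPKM, and Edem2 rose by less, with a log2 fold change of 0.51. The translocon subunit Sec61a1 fell from 39.8 ± 2.54 to 21.4 ± 0.701 FPKM and the co-chaperone Dnajb11 from 47.3 ± 3.19 to 33.9 ± 1.49 FPKM. Ssr1 was the other member that fell. The list median was −0.19 and camera placed the list lower (adjusted p = 0.03265; adjusted p = 0.2962 with an estimated correlation). The camera call ended in 5 of 21 alternatives, with adjusted p from 0.00732 to 0.212, among them those without Vehicle replicate 1 (0.0505), without Vehicle replicate 2 (0.061) and without KIRA6 replicate 2 (0.0652). Each of the fits without Vehicle replicate 1, Vehicle replicate 2, KIRA6 replicate 1, KIRA6 replicate 2 or KIRA6 replicate 3 called 1 member higher and 1 lower, and did not call Dnajb11. Median-ratio scaling called 1 higher and 6 lower, quantile normalization 2 and 1, the GC and length correction 3 and 11, and the fit without Vehicle replicate 3 and KIRA6 replicate 1 together 4 and 11.

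Of 8 tested transcripts reported to be cut by IRE1 (RIDD), 4 rose and 0 fell, over all genes and when adjusted over the list alone. Pmp22, a myelin and membrane protein, rose from 4.29 ± 0.661 to 23.03 ± 3.59 FPKM, with a log2 fold change of 2.29 ± 0.17 (SE, adjusted p = 0.0007236). The matrix proteins Sparc and Col6a1 rose from 27.9 ± 6.72 to 63.1 ± 9.81 FPKM and from 2.81 ± 1.37 to 12.4 ± 5.43 FPKM, and Ergic3 rose with a log2 fold change of 0.47. Bloc1s1, the best-known target of this decay, had 17.2 ± 4.55 and 25.4 ± 6.68 FPKM (adjusted p = 0.1815). Camera made no call (adjusted p = 0.102), and fry, which asks only for movement one way, did (adjusted p = 0.0009194). Of 21 alternatives, quantile normalization gave a camera call (adjusted p = 0.0174, in a range of 0.0174 to 0.455), and the GC and length correction called 3 members higher and 1 lower with a list median of 0.28 in place of 0.51. That correction also moved the median of all genes, from 0.16 to −0.002. Without Vehicle replicate 1, Vehicle replicate 2, KIRA6 replicate 2 or KIRA6 replicate 3, 2 members were called, and each of these fits ended the call for Col6a1.

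Among the 6 tested genes for KIRA6 targets and reported off-targets 1 rose and 1 fell (2 and 2 when adjusted over the list alone). The SRC-family kinase Lyn fell from 7.22 ± 0.857 to 3.13 ± 0.347 FPKM, and Fyn, of the same family, rose from 4.13 ± 0.414 to 6.25 ± 0.725 FPKM. The call for Fyn ended with median-ratio scaling and without Vehicle replicate 1, Vehicle replicate 2, KIRA6 replicate 2 or KIRA6 replicate 3, and camera made no call for the list (adjusted p = 0.2551).

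The other stress lists were mixed. Of the 16 tested ATF6-dependent chaperone and degradation genes 3 rose and 0 fell, over all genes and when adjusted over the list alone. Herpud1 rose from 4.73 ± 0.526 to 12.4 ± 0.556 FPKM, Ero1b from 1.43 ± 0.216 to 2.96 ± 0.491 FPKM and Hsp90b1 from 114.4 ± 6.41 to 166.5 ± 20.3 FPKM. The calls for Ero1b and Hsp90b1 ended without Vehicle replicate 1, Vehicle replicate 2, KIRA6 replicate 2 or KIRA6 replicate 3, which left 1 called member, and that for Hsp90b1 ended with median-ratio scaling. Median-ratio scaling and rescaling to TPM called 2 higher and 2 lower, and the GC and length correction 2 and 3. The list median was 0.036 while camera placed it lower without a call (adjusted p = 0.7973) and fry higher. That median lay near 0 and turned to −0.024 without Vehicle replicate 3 and −0.008 without KIRA6 replicate 1, and was 0.087, 0.086 and 0.008 without Vehicle replicate 2, KIRA6 replicate 2 and KIRA6 replicate 3. Of 35 tested genes of the integrated stress response 11 rose and 7 fell (12 and 10 when adjusted over the list alone). The balance turned to 8 higher and 10 lower with median-ratio scaling, 8 and 9 with rescaling to TPM and 10 and 10 with the GC and length correction, and 15 and 16 without Vehicle replicate 3 and KIRA6 replicate 1 together. Among the called members Ddit3, the factor CHOP, rose from 3.74 ± 0.692 to 9.84 ± 2.15 FPKM (adjusted p = 0.008107), and Ddit4, an inhibitor of mTORC1, from 5.79 ± 0.837 to 19.2 ± 0.969 FPKM. Atf4 mRNA had 58.2 ± 13.8 and 50.2 ± 11.8 FPKM (adjusted p = 0.5957). The amino acid transporter Slc1a5 fell from 40.01 ± 13 to 6.89 ± 1.21 FPKM and the folate enzyme Mthfd2 from 24.4 ± 1.67 to 10.5 ± 1.12 FPKM. The list had a median of −0.16 and a mean of 0.11, and camera made no call (adjusted p = 0.4617). Its median was −0.086 without Vehicle replicate 1, −0.069 without Vehicle replicate 3, −0.081 without KIRA6 replicate 1 and −0.06 without KIRA6 replicate 3. The fits without Vehicle replicate 2 or KIRA6 replicate 2 called 6 members of it higher and 2 lower, and those without Vehicle replicate 1 or KIRA6 replicate 3 called 3 lower.

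Heat shock genes of the HSF1 list split 3 higher and 3 lower among 18 tested (3 and 8 when adjusted over the list alone). The small chaperone Cryab rose from 6.23 ± 0.818 to 27.8 ± 2.53 FPKM and Hspa4l from 2.26 ± 0.0577 to 7.93 ± 1.14 FPKM, while Hsph1 fell from 32.9 ± 3.84 to 15.7 ± 1.9 FPKM. The remaining called members were Hspa1b, which rose and is uncertain because of its copy Hspa1a, and Hspa8 and Hspa4, which fell. The list median was −0.19 and its mean 0.006 (camera adjusted p = 0.1131), and the median was −0.41 without Vehicle replicate 3. Lower members numbered 1 without Vehicle replicate 1, Vehicle replicate 2 or KIRA6 replicate 2, 2 without KIRA6 replicate 3, 5 without KIRA6 replicate 1, 7 without Vehicle replicate 3 and 8 with median-ratio scaling. Of 21 tested NRF2 antioxidant genes 6 rose and 1, Osgin1, fell (6 and 2 when adjusted over the list alone). Gsta4 rose from 17.4 ± 1.08 to 34.8 ± 1.99 FPKM and heme oxygenase (Hmox1) from 4.30 ± 0.207 to 10.7 ± 2.61 FPKM. Ferritin light chain (Ftl1), which has near-identical pseudogenes, was at 1931 ± 139 and 3639 ± 309 FPKM. Camera made no call for the list (adjusted p = 0.2039), and the fits without Vehicle replicate 1, Vehicle replicate 2 or KIRA6 replicate 2 called 3 members higher. Quantile normalization, with 8 higher and 1 lower, gave a camera call (adjusted p = 0.0132, in a range of 0.0132 to 0.575 over 21 alternatives).

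Most tested ERK feedback and immediate-early genes fell. Of 30 tested members 23 fell and 2 rose (25 and 2 when adjusted over the list alone), and the list median was −1.47. Besides Dusp6, Areg, Ccnd1, Etv5 and Fosl1, the members that fell included the feedback inhibitors Spry1, Spry2, Spry4, Spred1 and Spred3, the phosphatases Dusp4 and Dusp5, Etv1 and Etv4. The immediate-early genes Fosb, Jun and Ier2 were also called lower. The members that rose were the AP-1 subunits Junb and Fosl2. Fos, Egr1, Egr2, Egr3, Myc, Dusp1, Dusp2, Dusp7, Spred2 and Ereg were either not tested or not called. Camera called the list lower (adjusted p = 5.019e-18; adjusted p = 0.1494 with an estimated correlation). With each single library left out in turn, 17 to 24 members were called lower. The number called higher was 1 without Vehicle replicate 1, Vehicle replicate 2, KIRA6 replicate 2 or KIRA6 replicate 3, and with median-ratio scaling, rescaling to TPM or the GC and length correction.

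**Figure D3:**
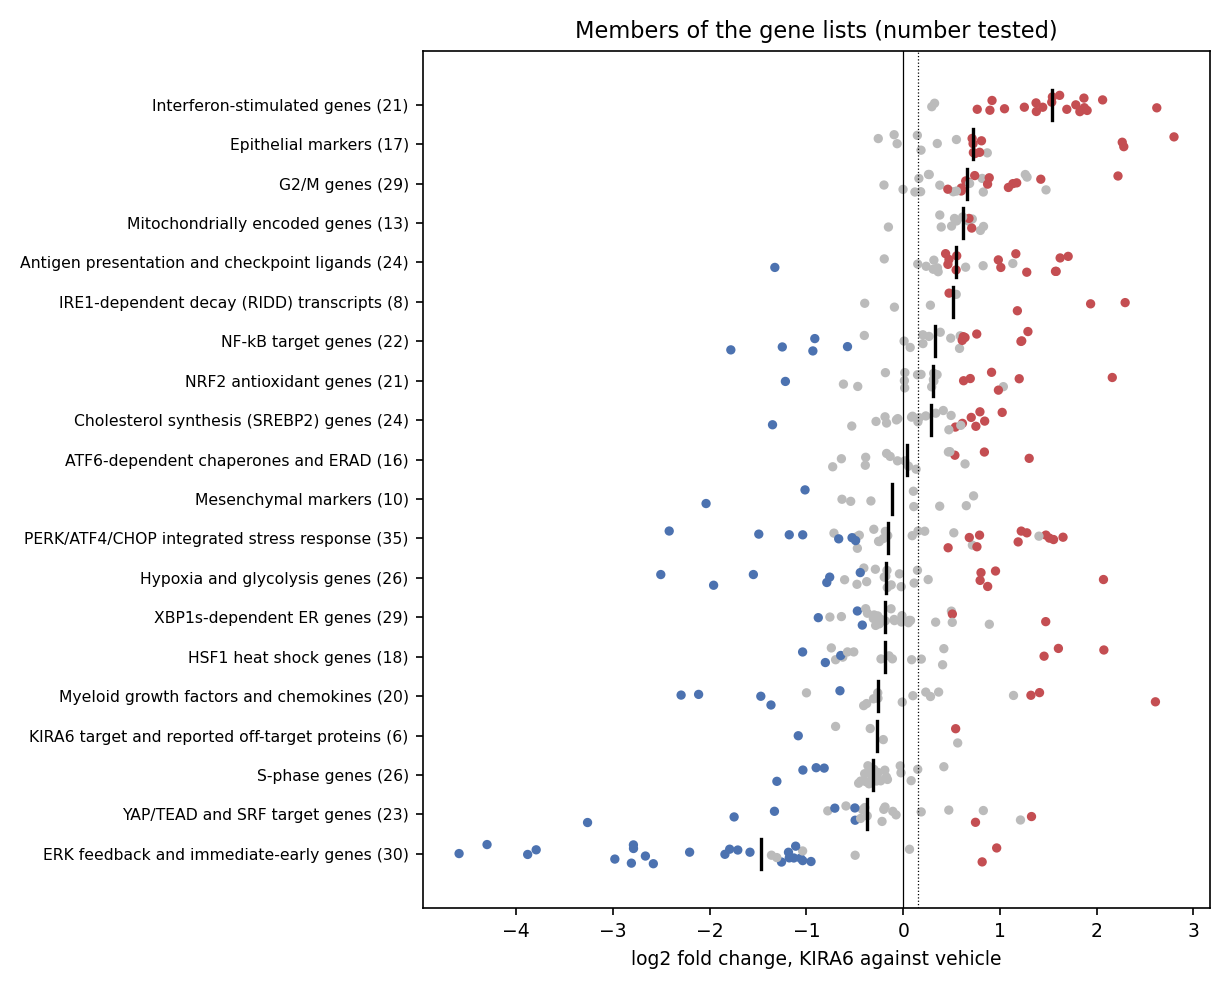
Each point is 1 tested member of a fixed gene list (number tested in parentheses), with its log2 fold change on the x axis; red and blue points were called higher and lower by limma, grey points were not called, the black bar is the list median and the dotted line the median of all tested genes (0.16). Interferon-stimulated genes (median 1.53) and ERK feedback genes (median −1.47) lie at the ends.

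Interferon-stimulated genes rose. Of 21 tested members 19 rose and 0 fell, over all genes and when adjusted over the list alone, with a list median of 1.53. The GTPase gene Gbp2 (chromosome 3, 142326363 to 142343769) rose from 1.41 ± 0.130 to 11.3 ± 1.71 FPKM, a log2 fold change of 2.62 ± 0.16 (SE, adjusted p = 0.000478), though its copy Gbp2b can share reads. Oasl1 rose from 3.03 ± 0.325 to 12.02 ± 1.23 FPKM and Ifit1 from 0.487 ± 0.111 to 3.62 ± 0.560 FPKM. Stat2, Irf7 and Irf9, which carry the interferon signal to DNA, were among the members that rose. Camera called the list higher (adjusted p = 2.957e-10), and this was the only list of the 20 called with an estimated correlation (adjusted p = 0.03766).

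Of 24 tested antigen presentation genes and checkpoint ligands 13 rose and 1, the poliovirus receptor gene Pvr, fell, over all genes and when adjusted over the list alone. Psmb9, a subunit of the immunoproteasome, rose from 1.03 ± 0.249 to 4.48 ± 0.820 FPKM. The class I genes H2-T23 and H2-Q4 rose from 3.88 ± 0.781 to 12.5 ± 0.797 FPKM and from 16.2 ± 1.68 to 36.8 ± 2.70 FPKM, and both are uncertain because class I genes share sequence. Cd274, which encodes PD-L1, was low, at 0.417 ± 0.0945 and 0.840 ± 0.0458 FPKM, and its log2 fold change of 0.55 ± 0.15 (SE) was close to the threshold (adjusted p = 0.04199). That call ended with median-ratio scaling and when any 1 library was left out. Camera called the list higher (adjusted p = 0.001293; adjusted p = 0.1249 with an estimated correlation). The count of higher members was 7 without Vehicle replicate 1, 5 without Vehicle replicate 2, 8 without KIRA6 replicate 1, 4 without KIRA6 replicate 2, 5 without KIRA6 replicate 3 and 6 with median-ratio scaling.

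The list closest to the series' question holds growth factors and chemokines that act on myeloid cells, and its members went both ways. Csf3 (ENSMUSG00000038067, chromosome 11, 98592089 to 98594455), which encodes the granulocyte colony-stimulating factor G-CSF, fell from 13.7 ± 1.65 to 2.82 ± 0.709 FPKM, a log2 fold change of −2.12 ± 0.20 (SE, adjusted p = 0.001322). Lif (chromosome 11, 4207557 to 4222514) fell from 10.5 ± 0.730 to 1.78 ± 0.505 FPKM (adjusted p = 0.0009124) and Tslp from 11.1 ± 2.41 to 3.63 ± 0.375 FPKM (adjusted p = 0.003042). Spp1 and Cx3cl1 also fell. In the other direction Cxcl5, a chemokine that attracts neutrophils (chromosome 5, 90907219 to 90909483), rose from 2.0 ± 0.389 to 15.8 ± 7.15 FPKM, a log2 fold change of 2.61 ± 0.36 (SE, adjusted p = 0.003899), and Cxcl10 and Ccl5 rose too. Csf1 had 29.0 ± 10.7 and 22.5 ± 2.89 FPKM (adjusted p = 0.435) and Cxcl1 had 2.45 ± 0.545 and 3.74 ± 2.49 FPKM (adjusted p = 0.5858). The sign of Cxcl1 turned without KIRA6 replicate 1, to −0.077.

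In that list 20 of 34 members were tested, of which 3 rose and 5 fell, over all genes and when adjusted over the list alone. The median was −0.26, but −0.076 without Vehicle replicate 3, −0.16 without KIRA6 replicate 1 and 0.036 with no filter on low values. Camera placed the list lower close to its threshold (adjusted p = 0.04223; adjusted p = 0.2664 with an estimated correlation). The camera call ended in 13 of 21 alternatives, with adjusted p from 0.0189 to 0.313, among them those without Vehicle replicate 3 (0.0949), without KIRA6 replicate 1 (0.0548), without KIRA6 replicate 3 (0.111) and without Vehicle replicate 3 and KIRA6 replicate 1 together (0.216). The fits without Vehicle replicate 2, KIRA6 replicate 1, KIRA6 replicate 2 or KIRA6 replicate 3 called 3 members lower. Cxcl2, Ccl2, Csf2 and Il6 were below the filter and were not tested. Csf2 had 0.253 ± 0.197 FPKM in vehicle and 0.0400 ± 0.0693 FPKM with KIRA6, where 3 fragments in the shallowest library correspond to 0.227 FPKM. Cxcl2 had 0.0467 and 0.0900 FPKM and Ccl2 0.153 and 0.380 FPKM, with 0.95 FPKM in KIRA6 replicate 1 alone. Il6 was listed at 0 in all vehicle libraries and at 0.0267 FPKM with KIRA6, below the 0.0749 FPKM of 3 fragments. A decrease in Il6 was therefore not detectable at this depth, and no rise above that floor was seen.

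**Figure D4:**
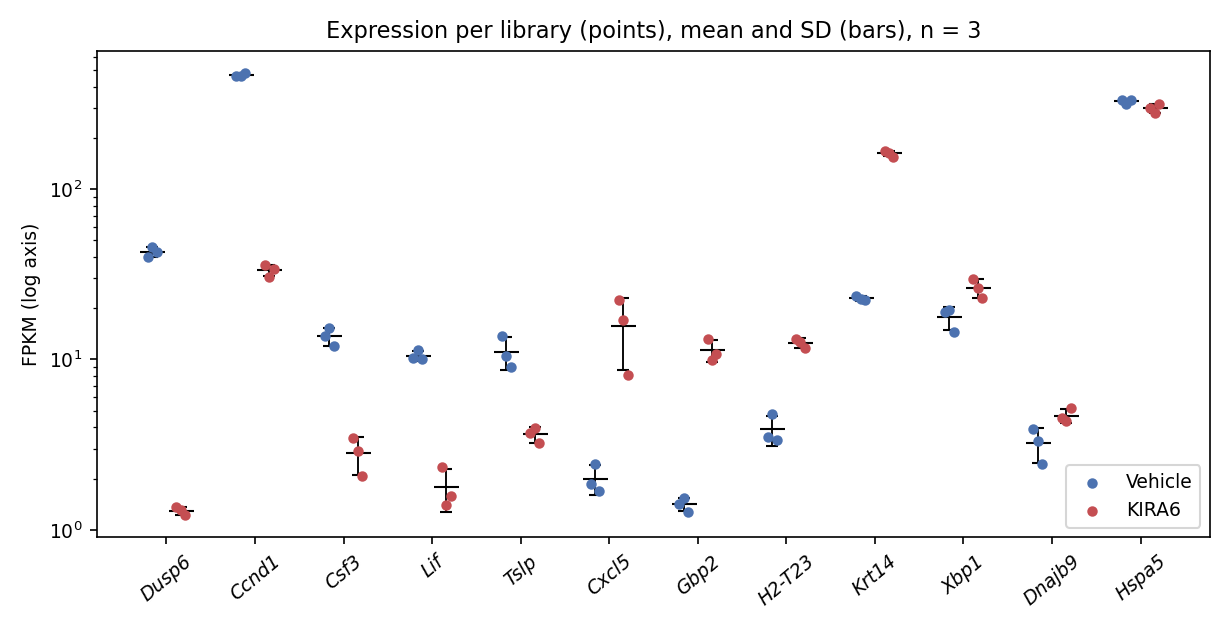
FPKM on a log axis for 12 genes, with 1 point per library, the mean as a horizontal bar and the SD as the error bar (n = 3 per group), vehicle in blue and KIRA6 in red. Csf3, Lif and Tslp lie lower with KIRA6 and Cxcl5, Gbp2 and Krt14 higher, while Dnajb9, Hspa5 and Xbp1 were not called.

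NF-kB target genes showed no common direction, with 7 of 22 tested members higher and 5 lower (8 and 5 when adjusted over the list alone). The transcription factor Irf1 rose from 8.17 ± 0.280 to 20.7 ± 1.56 FPKM. Tnfaip2 fell from 39.5 ± 2.17 to 11.1 ± 0.871 FPKM and Tnfaip3, the inhibitor A20, from 15.9 ± 1.52 to 6.40 ± 0.646 FPKM, and Bcl2l1, Sod2 and Vcam1 fell as well. Camera made no call (adjusted p = 0.9655). The balance was 4 higher and 6 lower with median-ratio scaling, 3 and 5 with quantile normalization, 5 and 6 with the GC and length correction, and 13 and 6 without Vehicle replicate 3 and KIRA6 replicate 1 together. With 1 library left out, higher members numbered 3 without Vehicle replicate 1, 2 without Vehicle replicate 2, 2 without KIRA6 replicate 2 and 4 without KIRA6 replicate 3.

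Of 26 tested S-phase genes 0 rose and 4 fell, over all genes and when adjusted over the list alone: Ccne1, from 13.3 ± 1.27 to 5.07 ± 0.512 FPKM, Cdc6, from 18.0 ± 2.43 to 8.46 ± 0.419 FPKM, Rrm2, from 140.9 ± 13.1 to 79.8 ± 7.65 FPKM, and Mcm3. Of 29 tested G2/M genes 13 rose and 0 fell (17 and 0 when adjusted over the list alone). The spindle protein Nusap1 rose from 7.96 ± 2.15 to 38.1 ± 1.9 FPKM, cyclin B2 (Ccnb2) from 63.2 ± 4.74 to 139.5 ± 15.0 FPKM and Hmmr from 7.39 ± 1.54 to 20.4 ± 1.64 FPKM. Camera called the S-phase list lower (adjusted p = 2.786e-05; adjusted p = 0.1494 with an estimated correlation) and the G2/M list higher (adjusted p = 7.062e-05; adjusted p = 0.1494 with an estimated correlation). The G2/M count was 8 without Vehicle replicate 1, 6 without Vehicle replicate 2, 5 without KIRA6 replicate 2, 6 without KIRA6 replicate 3 and 8 with median-ratio scaling. The S-phase count was 2 without KIRA6 replicate 2, where Rrm2 was no longer called, 8 with median-ratio scaling, and 18 without Vehicle replicate 3 and KIRA6 replicate 1 together.

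Epithelial markers rose, with 9 of 17 tested members higher and 0 lower, over all genes and when adjusted over the list alone. Krt14 rose from 22.9 ± 0.721 to 162.1 ± 6.10 FPKM and Krt19 from 22.4 ± 2.21 to 110.5 ± 6.70 FPKM, and the epithelial transcription factor Elf3 from 4.34 ± 1.49 to 22.2 ± 3.34 FPKM. Camera called the list higher (adjusted p = 0.001293; adjusted p = 0.1249 with an estimated correlation), and 5 members were called without KIRA6 replicate 2. Of 10 tested mesenchymal markers 0 rose and 2 fell, over all genes and when adjusted over the list alone. Vim fell from 468.4 ± 126 to 229.9 ± 47.1 FPKM and the matrix protease Mmp3 from 48.5 ± 8.88 to 11.5 ± 2.96 FPKM. Camera made no call for that list (adjusted p = 0.1254), and the Vim call ended without any 1 of Vehicle replicate 1, Vehicle replicate 2 or the KIRA6 libraries, which left 1 member called lower. Without Vehicle replicate 3 and KIRA6 replicate 1 together 3 mesenchymal markers were higher and 2 lower.

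Of 23 tested targets of YAP and SRF 6 fell and 2 rose, over all genes and when adjusted over the list alone. Ccn2, which encodes connective tissue growth factor, fell from 30.7 ± 12.2 to 2.65 ± 0.735 FPKM and Ankrd1 from 46.2 ± 5.43 to 18.0 ± 0.615 FPKM, while the myosin light chain Myl9 rose from 0.753 ± 0.217 to 2.62 ± 0.361 FPKM and Tpm1 rose as well. Camera called the list lower (adjusted p = 0.002548; adjusted p = 0.2962 with an estimated correlation). That call ended with library weights (adjusted p = 0.0556) and without Vehicle replicate 3 and KIRA6 replicate 1 together (adjusted p = 0.342, in a range of 0.000469 to 0.342 over 21 alternatives). In the fit without both libraries 9 members were higher and 8 lower and the list median was −0.13 in place of −0.37. The GC and length correction called 2 higher and 11 lower. The fits without Vehicle replicate 1, Vehicle replicate 2, KIRA6 replicate 1 or KIRA6 replicate 2 called 3 members lower.

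Metabolic genes went both ways. Of 26 tested hypoxia and glycolysis genes 5 rose and 6 fell (5 and 7 when adjusted over the list alone). Ndrg1 rose from 12.4 ± 0.826 to 53.6 ± 3.67 FPKM, while the glucose transporter Slc2a1 fell from 17.5 ± 3.49 to 4.11 ± 0.724 FPKM and Egln3 from 18.9 ± 2.58 to 6.09 ± 0.302 FPKM. Mxi1, Car9, Kdm3a and Bnip3 were the other members that rose. Camera placed the list lower (adjusted p = 0.02106; adjusted p = 0.2515 with an estimated correlation), a call that ended in 4 of 21 alternatives, with adjusted p from 0.013 to 0.0885. The fits without Vehicle replicate 2, KIRA6 replicate 2 or KIRA6 replicate 3 called 3 members higher and 3 lower, and the fit without Vehicle replicate 1 called 3 higher. Median-ratio scaling called 3 higher and 10 lower, and the fit without Vehicle replicate 3 and KIRA6 replicate 1 together 7 and 10. Of 24 tested genes of cholesterol synthesis 7 rose and 1 fell, over all genes and when adjusted over the list alone. Hmgcs1 rose from 23.8 ± 3.16 to 48.7 ± 4.49 FPKM and Mvk from 9.14 ± 0.668 to 15.7 ± 1.27 FPKM, and Tmem97 fell from 120.8 ± 9.68 to 47.1 ± 3.82 FPKM. Camera made no call for them (adjusted p = 0.2551), and median-ratio scaling called 3 members higher. Quantile normalization, with 6 higher and 1 lower, gave a camera call (adjusted p = 0.0414, in a range of 0.0414 to 0.464 over 21 alternatives). The number higher was 3 without Vehicle replicate 1, 1 without Vehicle replicate 2 or KIRA6 replicate 2, and 4 without KIRA6 replicate 1 or KIRA6 replicate 3, and the call for Mvk ended without Vehicle replicate 2 or KIRA6 replicate 2.

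Of the 13 mitochondrially encoded genes 2 rose and 0 fell, over all genes and when adjusted over the list alone. mt-Co2 had 24.7 ± 1.26 and 40.2 ± 7.14 FPKM and mt-Cytb 2874 ± 301 and 4723 ± 828 FPKM. Camera placed the list higher (adjusted p = 0.03265; adjusted p = 0.2962 with an estimated correlation), and the correction for GC content and length ended that call (adjusted p = 0.205), as did leaving out Vehicle replicate 2 (0.0657) or KIRA6 replicate 2 (0.0652). No member was called under median-ratio scaling or without Vehicle replicate 1, Vehicle replicate 2, KIRA6 replicate 2 or KIRA6 replicate 3. Of 25 markers of leukocytes, fibroblasts and endothelium 2 had a mean of at least 0.5 FPKM, and both were called higher, over all genes and when adjusted over the list alone. Pdgfra had 0.533 ± 0.163 and 2.75 ± 0.945 FPKM and Cd68 2.0 ± 0.527 and 3.42 ± 0.370 FPKM, and the call for Cd68 ended with median-ratio scaling and without any 1 library except Vehicle replicate 3. No other marker exceeded 0.75 FPKM in any library. In all, camera called 11 of 20 lists, 5 higher and 6 lower, of which 1 was called with an estimated correlation, and fry called 12.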

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

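The tests without both libraries that stand apart, with the residual covariate, with voom and with the GC and length correction were chosen only after the results were seen. Under the 21 alternatives to the fit, 0 genes called both there and as reported had opposite signs, and 6 of the 11 called lists were called in each. Of 1698 values of 81 named genes 1595 kept their direction and their side of the threshold, 82 lost and 15 gained a call, and 6 reversed. Of 74 called named genes 62 were called in every alternative that tested them. The naming rule favours large changes and small p, so these 74 do not measure the stability of all calls. With 1 library left out, from 1204 (without KIRA6 replicate 2) to 2540 (without Vehicle replicate 3) of the 2783 called genes were still called. The 6 values of named genes that reversed belong to uncalled genes, and their cause was not tested. Ern1 was 0.24 with library weights and 0.33 without Vehicle replicate 3 and KIRA6 replicate 1. Csf1 was 0.08 and Cxcl1 −0.21 without those libraries. With each library left out in turn, Ern1 ran from −0.55 to 0.071 and Cxcl1 from −0.077 to 0.80.

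Called genes numbered 2783 as reported and from 1211 to 3392 with each library left out in turn, the highest without Vehicle replicate 3, and the cause was not tested. Library weights gave 10003 genes and 2163 changed at least 2-fold, from weights whose estimate stopped before converging. That fit is among the 21 alternatives and sets an end of the adjusted p range for lists that include XBP1s (0.00732), myeloid (0.313), RIDD (0.455) and cholesterol (0.464). Without Vehicle replicate 3 and KIRA6 replicate 1 the numbers were 6610 and 2304, and the residual covariate gave 6751. Both fits take out the main within-group spread as found in these same data. The rise in calls was therefore built in and is no evidence that more genes changed. Camera called 1 of 20 lists with an estimated correlation. That correlation was 0.395 for the ERK list. For the epithelial, antigen presentation and interferon lists it was −0.045, −0.01 and −0.027, below the preset 0.01. The unadjusted camera p of the epithelial list still went from 0.0003878 to 0.01874. A larger p with this version therefore does not by itself show that correlation between genes made a call. Quantile normalization added calls for the RIDD, NRF2 and cholesterol lists. It ended those for the XBP1s, myeloid and hypoxia lists (camera adjusted p = 0.212, 0.0848 and 0.0531). The replicate block gave 4423 genes, and 4914 together with the GC and length correction. Deviations of same-numbered samples correlated at 0.76, −0.47 and 0.74. Vehicle replicates 1 and 3 correlated best with the KIRA6 library of their own number, and Vehicle replicate 2 with KIRA6 replicate 1 (0.71). Whether the numbers pair the samples therefore stays open. The other settings gave 2084 to 3353 called genes and 888 to 1636 changed at least 2-fold. Scaling moved the balance of higher and lower calls, to 59.6% higher with rescaling to TPM and 47.4% with median-ratio scaling, from 66.2%. The planned test of raw counts was not run because the deposited values are FPKM. The filter at 0.5 FPKM left Csf2, Il6, Ccl2 and Cxcl2 untested, and without a filter 23 interferon-stimulated genes were called higher, against 19. Depth limits genes at or below 3 fragments, such as Il6.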

Other observations

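The gene families and the list of short-lived transcripts below, and the test of exchanged labels, were chosen only after the results were seen. Among 15 families picked by symbol, ribosomal protein genes (Rpl, Rps) had 2 members higher and 0 lower of 93 tested (camera adjusted p = 0.524), and 0 higher and 2 lower with median-ratio scaling, which shifts all genes, so no direction is read from them. Of 19 tested nucleolar processing genes (Nop, Utp) 12 fell and 1 rose, with a median log2 fold change of −0.77 (camera adjusted p = 1.14e-08; adjusted p = 0.16 with an estimated correlation). Of 51 translation initiation factor genes (Eif) 10 fell and 2 rose, and of 32 RNA polymerase subunit genes (Polr) 8 fell and 2 rose (camera adjusted p = 5.82e-06 and 4.43e-05; adjusted p = 0.26 for both with an estimated correlation). With median-ratio scaling 15, 19 and 8 of them fell.

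Kinesin genes (Kif), motors of which many act on the spindle, rose in 13 of 29 cases and fell in 0, and all 4 tested guanylate-binding protein genes (Gbp) rose, with a median of 2.01 (camera adjusted p = 0.000112 for both; adjusted p = 0.447 and 0.16 with an estimated correlation). Kif11, Kif20a, Gbp2 and Gbp3 are also called members of the G2/M and interferon lists, so these families partly restate those lists. With median-ratio scaling 9 kinesin genes and the same number of Gbp genes, 4, were higher. Of 38 short-lived transcripts outside the ERK list 15 rose and 3 fell. Those that rose included Id2, Id3, Gadd45a, Gadd45b and Klf2, with log2 fold changes of 2.72, 2.14, 2.16, 2.22 and 2.0, and those that fell were Sgk1, Mcl1 and Csrnp1.

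The decrease of ERK feedback genes was weighed against a general loss of short-lived transcripts and against GC content and length. Short-lived transcripts outside the list had a median log2 fold change of 0.63 (95% bootstrap interval over genes 0.17 to 0.89), above the 0.16 of all genes. A loss common to those 38 transcripts, of which 6 are also in other fixed lists, was therefore not seen. The 38 were chosen after the results were seen, and Irf1 and Atf3 among them were called higher in other lists. They therefore cannot decide whether short-lived transcripts in general were lost. The interval treats the genes as independent and does not measure the spread between libraries. After each library was corrected for GC content and length, 23 of the 23 members called lower were still called, and the list median went from −1.47 to −1.71, which argues against that bias. The correction also moved the median of all genes from 0.16 to −0.002, so part of the move in the list median was common to all genes. A candidate explanation is lower output of the ERK pathway in KIRA6-treated 4T1 cells, a hypothesis that these data did not test, since phosphorylation was not measured. A measurement of phosphorylated ERK, with and without IRE1, would test it.

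Vehicle replicate 3 and KIRA6 replicate 1 lay apart on an axis with 81.3% of the within-group variance, with scores of 0.63 and −0.50 against −0.38 and −0.25 for the other vehicle and 0.17 and 0.33 for the other KIRA6 libraries. Exchanged labels are argued against: on a scale where the other vehicle libraries are 0 and the other KIRA6 libraries 1, Vehicle replicate 3 lay at −0.41 by its ERK list. Leukocytes, fibroblasts and endothelium in Vehicle replicate 3 are argued against too. Of their 25 markers 0 reached 0.5 FPKM there and lay at least 2-fold above the other vehicle libraries. Collagen genes (Col) had a median loading of 2.24 on the axis, toward Vehicle replicate 3. Col1a1, Col1a2 and Col3a1 were at 0.04, 0.02 and 0 FPKM there. Other kinds of cell, such as other epithelial cells, were not tested for. GC content and length together explained 33.2% of the variance of the genes' loadings, consistent with a contribution of library composition, but correcting for them left 68.5% of the within-group variance. What sets the rest apart stays open, and the design names no biological difference between replicates to test.

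The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share below 0.05. For called genes the labelled split gave 2783 and the highest other 1133, for genes changed at least 2-fold 1172 and 714, and for called lists 11 and 9. In each case 1 of 10 splits, the labelled one, gave a result as large. The split with 1133 genes set Vehicle replicates 1 and 2 with KIRA6 replicate 1 against the rest, along the axis described here.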
